A study of Zea mays with 18 samples.

How the data were processed

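Gene expression was measured by RNA sequencing of total RNA from quiescent centres isolated from maize root tips, in 18 libraries: WT, the ZmPgb1.1 overexpressing line S and the ZmPgb1.1 down-regulated line A, each at 0 h under normoxia and after 12 h under hypoxia, with 3 libraries per group. Group and replicate number of each library were taken from its title, and the 18 columns of the deposited table matched these titles exactly. The labels do not say whether the 3 libraries of a group came from separate pools of seedlings, so p-values measure only the spread between these libraries, which may be technical.

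The values analysed are whole-number read counts per gene as deposited, not normalised, in 1 table of 28724 gene IDs. Per the submitters' processing notes, HISAT2, featureCounts and the B73 RefGen_v4 build were used to make these counts. Tool versions, strand setting, treatment of reads that map to several places and any filter are not given in the sources used here. Near-identical gene copies, overlapping genes and antisense genes are therefore uncertain, since reads could have been shared or left out. Of the IDs, 28675 begin with Zm00001d and 49 with GRMZM5G, all end in RefGen_V4, and 3186 rows had 0 counts in every library. The table pairs no ID with a name, and 0 IDs matched the table of maize gene names used here, which belongs to another assembly. For this reason ZmPgb1.1 and the 37 gene lists fixed before the data were examined (among them fermentation, glycolysis, phytoglobins, stem cell regulators and markers of other root cells) were not tested, and no gene set test or its alternatives (an estimated inter-gene correlation, a replicate block) was run.

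Total counts per library ran from 35441975 to 89759585. The 100 most abundant genes took 12.8 to 15.0% of the counts, and normalisation factors ran from 0.975 to 1.023. A level of 3 counts, used as the floor below which a gene was read as off, was 0.0334 to 0.0846 CPM. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

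Tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr by group, which kept 20945 and removed 7779, libraries were scaled by TMM, and a negative binomial model with 1 mean per group was fitted to all 18 libraries with robust quasi-likelihood dispersion (12 residual degrees of freedom). The 10 contrasts were 3 hypoxia responses (12 h against 0 h in each line), 4 comparisons of a line with WT at 1 time, and 3 differences between lines in the response to hypoxia. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Standard errors of log2 fold changes were computed from the fold change and its F statistic. CPM values are counts per 1000000 of the TMM-scaled library size, given as mean ± SD. Where the lower group held more than 4 counts, a ratio of mean CPM is given as the fold. The design, the rule for named genes and the alternative settings were fixed before the data were examined. That rule, with no gene names at hand, took per contrast at most 2 rising and 2 falling IDs with the largest log2 change among called genes whose higher group averaged at least 10 CPM and, except in differences of responses, whose groups did not overlap. IDs named outside this rule are said to be chosen after their values were seen.

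The fit was tested on simulated counts with the means, dispersions and library sizes of the real data, in which 200 genes were changed. For the WT response to hypoxia, over 20641 genes, 15.4% of genes changed 1.5-fold, 54.5% changed 2-fold and 69.2% changed 4-fold were recovered, with 5 false calls in all. For the difference between line S and WT in the response these shares were 3.08%, 31.8% and 63.1%, with 6 false calls. In 5 simulations with no change, no contrast had more than 1 call, with all libraries or after the library least like its group had been left out of every group. These simulated libraries differ within a group by random scatter alone, so this says nothing about libraries that carry a wrong label.

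Libraries were compared by Spearman correlation of log2 CPM (prior count 2), by principal components of the 500 most variable genes and by a chi-square statistic of their counts. No 2 libraries agree within sampling noise: the lowest chi-square per gene over the 153 pairs was 3.89, where about 1 is the value for repeat counts of 1 library. The 8 alternative settings fixed in advance were DESeq2 1.42.0, RLE scaling, no low-count filter, a stricter filter (at least 1 CPM in all 3 libraries of a group and a mean of 10 CPM in a group), the replicate number as a block, a fit with only the groups compared, limma-voom, and leaving out each library in turn. An alternative added after seeing the data left out the 6 libraries whose 2 nearest libraries carry another label and kept the labels of the other 12, 2 per group. Removing the library least like its group lowers the spread by construction. The biological coefficient of variation was 35.2% with 18 libraries and 6.97% with 12 (6 residual degrees of freedom). How much of this fall comes from the selection itself was not measured. Adjusted p-values of that fit are too small to the extent that the libraries left out are true replicates. No library was moved to another group. For the comparisons that share WT libraries, a reference value came from the simulations with no change, in which the WT libraries were simulated too. The median log2 change over all genes lay within 0.1 of 0 in every contrast under both scalings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.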

Results

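Total RNA was sequenced from the quiescent centre, the small group of slowly dividing stem cells at the tip of the maize root, in seedlings that were 5 days old. The plants were wild type (WT), a line overexpressing the phytoglobin gene ZmPgb1.1 (line S) or a line in which it was down-regulated (line A). Phytoglobins are plant hemoglobins that remove nitric oxide, and ZmPgb1.1 belongs to this family. Roots were taken at 0 h under normoxia or after 12 h under hypoxia, in a solution supplied with 4% oxygen. The 3 lines and 2 times make 6 groups, written WT_0h, WT_12h, S_0h, S_12h, A_0h and A_12h, with 3 libraries each and 18 in all. Libraries held 35441975 to 89759585 counts and between 21120 and 22265 genes with at least 1 count. A level of 3 counts corresponded to 0.0334 to 0.0846 CPM (counts of a gene per 1000000 counts of its library), depending on the library. The design asks what 12 h of hypoxia changed in each line, what the altered phytoglobin level changed at each time, and whether the response to hypoxia differed between lines. No group was kept in air for 12 h, so oxygen and time cannot be separated. The counts of ZmPgb1.1 are not analysed here, because no gene ID in the counts could be paired with a gene name, and the labels of the lines were therefore not checked against their target gene. Genes are given by the ID in the deposited table, without names or functions.

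The labelled groups did not match the groups in which the libraries resembled each other. The gene Zm00001d044156.RefGen_V4 shows the pattern: it measured 374 and 372 CPM in S_12h replicates 1 and 2 and 5.67 CPM in S_12h replicate 3, while A_12h replicate 3 held 359 CPM and A_12h replicates 1 and 2 held 3.69 and 3.97 CPM. In the same way, Zm00001d042684.RefGen_V4 was at 50.6 and 44.9 CPM in A_0h replicates 1 and 2, at 47.9 CPM in S_12h replicate 3 and at 0.114 CPM in A_0h replicate 3. Across genes, the 18 libraries fell into 6 sets of 3, within which each library had its 2 highest Spearman correlations. The correlation with the second nearest library was at least 0.9964 and that with the third nearest at most 0.991, whereas it ranged from 0.9351 to 0.9981 within the labelled groups. None of the sets was a labelled group: 0 of the 18 libraries had both nearest libraries in its own group, 12 had 1 and 6 had none. These 6 were 1 library of each group, and each had both nearest libraries in 1 other group. WT_0h replicate 2 was nearest to WT_12h, WT_12h replicate 3 to S_0h, and S_0h replicate 3 to WT_0h. S_12h replicate 3 was nearest to A_0h, A_0h replicate 3 to A_12h, and A_12h replicate 3 to S_12h. The first principal component took 49.9% of the variance of the 500 most variable genes and set A_0h replicates 1 and 2 and S_12h replicate 3, at 91.4 to 91.6, apart from the other libraries, all of which lay below 0. Below, every group means the libraries that carry its label, and each comparison is also given without these 6 libraries, an alternative chosen after seeing the data.

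**Figure D1:**
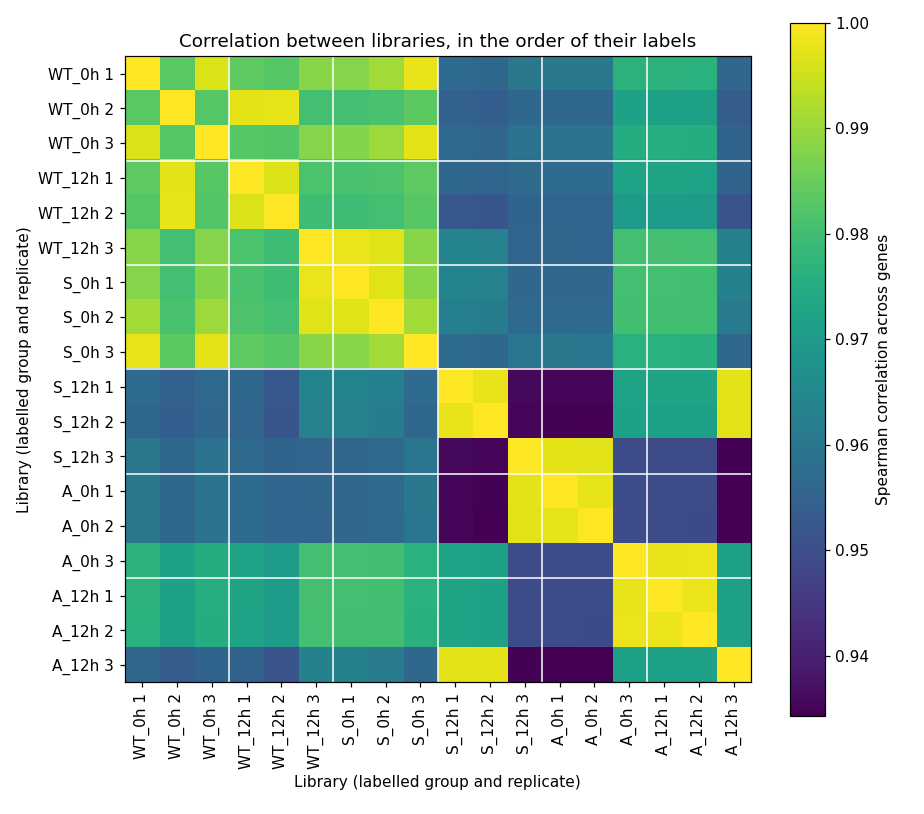
Spearman correlation across genes between all 18 libraries, in the order of their labels, with white lines between the labelled groups. The bright squares of 3 libraries cross the white lines, and S_12h replicate 3 correlates at 0.9972 with A_0h replicate 1 but at no more than 0.9356 with the other S_12h libraries.

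In line S, 12 h of hypoxia went with higher levels of Zm00001d044156.RefGen_V4, from 0.156 ± 0.212 CPM in S_0h to 250.6 ± 212 CPM in S_12h (SD, n = 3), a 1600-fold ratio of means, and its log2 fold change was 10.57 (SE 2.23, adjusted p = 0.0158). Zm00001d042684.RefGen_V4 rose from 0.0178 ± 0.0155 to 16.1 ± 27.6 CPM (log2 fold change 9.73, SE 2.67, adjusted p = 0.0383), a mean carried by the 47.9 CPM of S_12h replicate 3, without which its log2 fold change was 3.02 (adjusted p = 0.347). Zm00001d051244.RefGen_V4 fell from 10.3 ± 3.36 to 0.159 ± 0.0108 CPM, a 65-fold ratio of means (log2 fold change -6.0, SE 1.60, adjusted p = 0.0347). Zm00001d041662.RefGen_V4 fell from 122.1 ± 58.8 to 15.03 ± 0.723 CPM, an 8.12-fold ratio (log2 fold change -3.02, SE 0.77, adjusted p = 0.0303). In all, 1822 of 20945 genes passed the threshold, 1001 higher and 821 lower under hypoxia, of which 475 rose and 117 fell by at least 2-fold. The 2 groups did not overlap in 28.7% of the genes tested, where chance alone gives 10% on average over groupings. Genes vary together across libraries, so the share for a single grouping can lie far from 10% by chance. Here and in the comparisons below, the 10% is therefore a reference and no test. The number called depended on single libraries: it was 491, 228 and 422 without S_0h replicate 1, 2 or 3, 236 and 266 without S_12h replicate 1 or 2, and 6074 without S_12h replicate 3. It was 166 with only the groups compared in the fit and 3769 by DESeq2. The called genes were more often lower by limma-voom (943 higher, 969 lower) and without S_0h replicate 1 (214, 277), S_0h replicate 2 (110, 118) or S_12h replicate 3 (3007, 3067). They were 5803 higher and 5747 lower without the 6 libraries nearest to another group. Zm00001d042684.RefGen_V4 lost its call without any of the 6 libraries, and the other 3 IDs kept theirs only without S_12h replicate 3. By limma-voom the calls of Zm00001d044156.RefGen_V4 (adjusted p = 0.47), Zm00001d042684.RefGen_V4 (log2 fold change 5.44, adjusted p = 0.697) and Zm00001d051244.RefGen_V4 (adjusted p = 0.209) were also lost. That of Zm00001d044156.RefGen_V4 was lost with only the groups compared in the fit (adjusted p = 0.0727), and that of Zm00001d042684.RefGen_V4 with no low-count filter (adjusted p = 0.0504). The log2 fold change of Zm00001d044156.RefGen_V4 was 12.8 without S_0h replicate 3. Leaving out the 6 libraries nearest to another group gave 11550 of 21030 genes, among them 1814 of the 1822 with the same direction. Because that fit uses a part of the same libraries, shared calls here and in the comparisons below are no separate support. In that fit the log2 fold changes of the 4 IDs were 13.38, 2.41, -5.66 and -3.40.

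In WT, no gene passed the threshold between WT_0h and WT_12h by edgeR with all 18 libraries (0 of 20945), with 379 genes at an unadjusted p under 0.05 and 0 called by limma-voom, while DESeq2 called 7. The groups did not overlap in 8.68% of genes, below the 10% that chance gives. The count stayed at 0 when any 1 of the 6 WT libraries was left out. A total of 6138 genes were called without the 6 libraries nearest to another group, 2859 higher and 3279 lower in WT_12h. The 4 IDs given next were taken from that fit, after their values were seen. Zm00001d034688.RefGen_V4 measured 24.9 ± 3.31 CPM in WT_12h replicates 1 and 2 and had 0 counts in WT_0h replicates 1 and 3 (SD, n = 2), while the libraries left out ran the other way, with 0.909 CPM in WT_12h replicate 3 and 24.3 CPM in WT_0h replicate 2. Zm00001d030914.RefGen_V4 was at 16.9 ± 2.62 CPM against 0, and at 0 and 18 CPM in the same left-out libraries. Zm00001d018925.RefGen_V4 had 0 counts in WT_12h replicates 1 and 2, 247 ± 78.3 CPM in WT_0h replicates 1 and 3, 181 CPM in WT_12h replicate 3 and 0.0274 CPM in WT_0h replicate 2. Zm00001d002475.RefGen_V4 had 0 counts against 45.5 ± 0.239 CPM, with 44.7 CPM in WT_12h replicate 3 and 0 in WT_0h replicate 2.

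In line A, no gene passed the threshold between A_0h and A_12h with all libraries by edgeR (0 of 20945, lowest adjusted p = 0.257), although 4021 genes had an unadjusted p under 0.05 and the groups did not overlap in 17.8% of genes against 10% by chance. DESeq2 called 171 genes, 166 of them lower under hypoxia, and limma-voom called 0. A single library decided this count: without A_0h replicate 3, edgeR called 5112 genes, 2754 higher and 2358 lower, and without any other library of the 2 groups it called 0. Without the 6 libraries nearest to another group it called 12514, 6506 higher and 6008 lower, from which the 4 IDs that follow were taken after their values were seen. Zm00001d038523.RefGen_V4 measured 12.5 ± 0.83 CPM in A_12h replicates 1 and 2 against 0.0175 ± 0.00014 CPM in A_0h replicates 1 and 2 (SD, n = 2), with 0.0551 CPM in A_12h replicate 3 and 12.1 CPM in A_0h replicate 3. Zm00001d004509.RefGen_V4 measured 38.8 ± 2.41 against 0.158 ± 0.0756 CPM, with 3.94 and 40.3 CPM in the same 2 libraries. Zm00001d011601.RefGen_V4 and Zm00001d032472.RefGen_V4 were at 73.3 ± 1.17 and 61.9 ± 0.782 CPM in A_0h replicates 1 and 2, and both had 0 counts in every A_12h library and in A_0h replicate 3.

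Before hypoxia, no gene passed the threshold between S_0h and WT_0h with all libraries by edgeR (0 of 20945, 355 at an unadjusted p under 0.05), limma-voom also called 0, and DESeq2 called 13, 3 higher and 10 lower in line S. The groups did not overlap in 9.33% of genes against 10% by chance, and the count stayed at 0 when any 1 of the 6 libraries was left out. With the 6 libraries nearest to another group left out, 4232 genes were called, 2062 higher and 2170 lower in line S, and the IDs given here were chosen from that fit after their values were seen. Zm00001d013231.RefGen_V4 was at 15.0 ± 0.514 CPM in S_0h replicates 1 and 2 and at 1.38 ± 0.595 CPM in WT_0h replicates 1 and 3 (SD, n = 2), with 1.37 CPM in S_0h replicate 3 and 10 CPM in WT_0h replicate 2. Zm00001d047124.RefGen_V4 was at 71.6 ± 14.6 against 11.6 ± 8.11 CPM, with 10.6 and 12.4 CPM in those 2 libraries. Zm00001d018161.RefGen_V4 was at 0.406 ± 0.0256 CPM in S_0h replicates 1 and 2 against 70.7 ± 2.35 CPM in WT_0h replicates 1 and 3, with 72.9 CPM in S_0h replicate 3 and 57.1 CPM in WT_0h replicate 2. Zm00001d009351.RefGen_V4 was at 0.76 ± 0.0843 against 48.9 ± 8.61 CPM, with 49.3 and 5.28 CPM in the left-out libraries of S_0h and WT_0h.

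After 12 h of hypoxia, Zm00001d044156.RefGen_V4 was higher in line S than in WT, at 250.6 ± 212 against 0.17 ± 0.151 CPM (SD, n = 3; log2 fold change 10.59, SE 2.24, adjusted p = 0.0118), a 1480-fold ratio of means. Zm00001d022081.RefGen_V4 was at 11.2 ± 5.47 CPM in S_12h, while the 3 WT_12h libraries held 2 counts of it together (log2 fold change 10.09, SE 2.16, adjusted p = 0.0126, a fitted value that depends on the prior count). Zm00001d051472.RefGen_V4 was lower in S_12h, at 0.948 ± 0.149 against 36.99 ± 29.3 CPM in WT_12h, a 39-fold ratio (log2 fold change -5.28, SE 1.48, adjusted p = 0.0364). WT_12h replicates 1 and 2 held 50.7 and 56.8 CPM of it and replicate 3 only 3.37 CPM. Zm00001d031657.RefGen_V4 was at 15.03 ± 20.6 against 164.4 ± 89.2 CPM, a 10.9-fold ratio (log2 fold change -3.46, SE 1.03, adjusted p = 0.0447). S_12h replicate 3 held 38.8 CPM of it and replicates 1 and 2 held 2.75 and 3.53 CPM. Without replicate 3 the log2 fold change was -5.71. A total of 2370 genes passed the threshold, 1300 higher and 1070 lower in line S, and the groups did not overlap in 26.9% of genes, where chance gives 10%. The count was 442, 353 and 2316 without WT_12h replicate 1, 2 or 3, 586 and 529 without S_12h replicate 1 or 2, and 5990 without S_12h replicate 3. With only the groups compared in the fit it was 85, and by DESeq2 4058. More genes were lower than higher in line S by limma-voom (1158 higher, 1162 lower) and without WT_12h replicate 1 (206, 236), WT_12h replicate 2 (158, 195) or S_12h replicate 3 (2971, 3019). Both higher IDs lost their call without WT_12h replicate 1 or 2, and both lower IDs kept it only without WT_12h replicate 3 or S_12h replicate 3. Under limma-voom, adjusted p was 0.434 for Zm00001d044156.RefGen_V4, 0.239 for Zm00001d022081.RefGen_V4 and 0.309 for Zm00001d051472.RefGen_V4, which ended these calls. The fit of only the groups compared ended those of Zm00001d044156.RefGen_V4 (0.0813), Zm00001d051472.RefGen_V4 (0.0931) and Zm00001d031657.RefGen_V4 (0.183), and no low-count filter that of Zm00001d031657.RefGen_V4 (0.0585). The log2 fold change of Zm00001d044156.RefGen_V4 was 11.53 without WT_12h replicate 2. That of Zm00001d022081.RefGen_V4 was 12.57 without WT_12h replicate 3. Without the 6 libraries nearest to another group the count was 12298 (6334 higher, 5964 lower), which included 2354 of the 2370 genes with the same direction. The log2 fold changes of the 4 IDs were then 10.85, 12.98, -5.73 and -6.11.

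At 0 h, Zm00001d042684.RefGen_V4 was higher in line A than in WT, at 31.8 ± 27.6 against 0.017 ± 0.0295 CPM (SD, n = 3; log2 fold change 10.63, SE 2.72, adjusted p = 0.0471), where A_0h replicate 3 held only 0.114 CPM. The WT_0h level rested on 4 counts, all in replicate 1, so no fold is given. Without that library the log2 fold change was 14.08 (adjusted p = 0.146). Zm00001d011394.RefGen_V4 was at 10.02 ± 8.52 against 0.0968 ± 0.0586 CPM, a 104-fold ratio (log2 fold change 6.66, SE 1.67, adjusted p = 0.0431). A_0h replicates 1 and 2 held 15.1 and 14.7 CPM of it and replicate 3 only 0.186 CPM. Zm00001d018340.RefGen_V4 was lower in line A, at 4.45 ± 2.86 against 16.4 ± 2.8 CPM, a 3.69-fold ratio (log2 fold change -1.88, SE 0.39, adjusted p = 0.0215). Zm00001d050214.RefGen_V4 was at 2.95 ± 0.872 against 10.2 ± 6.28 CPM, a 3.48-fold ratio (log2 fold change -1.80, SE 0.43, adjusted p = 0.0375). In all, 696 genes passed the threshold, 314 higher and 382 lower in line A. Of these, 163 were higher and 44 lower by at least 2-fold. DESeq2, which called 2305, put 56.2% of its calls higher against 45.1% by edgeR. With only the groups compared in the fit, 23 were higher and 10 lower (33 in all), and without A_0h replicate 2, 90 were higher and 82 lower. The groups did not overlap in 25.8% of genes, where chance gives 10%. Without WT_0h replicate 1, 2 or 3 the count was 267, 324 or 159, without A_0h replicate 1 or 2 it was 169 or 172, and without A_0h replicate 3 it was 3083. Both higher IDs kept their call only without A_0h replicate 3, Zm00001d018340.RefGen_V4 only without WT_0h replicate 2 or A_0h replicate 3, and Zm00001d050214.RefGen_V4 only without WT_0h replicate 1 or A_0h replicate 3. Calls ended by limma-voom were those of Zm00001d042684.RefGen_V4 (adjusted p = 0.612), Zm00001d011394.RefGen_V4 (0.39) and Zm00001d050214.RefGen_V4 (0.116). Those ended with only the groups compared in the fit were Zm00001d011394.RefGen_V4 (0.132), Zm00001d018340.RefGen_V4 (0.128) and Zm00001d050214.RefGen_V4 (0.145). With no low-count filter, Zm00001d042684.RefGen_V4 (0.0627) and Zm00001d011394.RefGen_V4 (0.0556) lost theirs. The log2 fold change of Zm00001d011394.RefGen_V4 was 7.27 and that of Zm00001d050214.RefGen_V4 -1.17 without WT_0h replicate 2, and that of Zm00001d018340.RefGen_V4 was -2.55 without A_0h replicate 3. Without the 6 libraries nearest to another group the count was 10351 (5222 higher, 5129 lower), which included all 696 genes with the same direction. The 4 IDs then had log2 fold changes of 10.65, 7.85, -2.67 and -0.94.

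After 12 h of hypoxia, Zm00001d022081.RefGen_V4 was at 38.96 ± 19.2 CPM in A_12h, against 2 counts in all 3 WT_12h libraries (SD, n = 3; log2 fold change 11.89, SE 2.20, adjusted p = 0.0107, a fitted value that depends on the prior count). Zm00001d044156.RefGen_V4 was at 122.1 ± 205 against 0.17 ± 0.151 CPM, a 719-fold ratio of means carried by A_12h replicate 3 (log2 fold change 9.55, SE 2.18, adjusted p = 0.0234), without which its log2 fold change was 4.56 (adjusted p = 0.0857). Zm00001d050214.RefGen_V4 was lower in line A, at 2.19 ± 0.508 against 13.4 ± 6.32 CPM, a 6.13-fold ratio (log2 fold change -2.61, SE 0.45, adjusted p = 0.00797), and kept its call whichever of the 6 libraries was left out. Zm00001d022085.RefGen_V4 was at 41.2 ± 7.62 against 135.5 ± 48.9 CPM, a 3.29-fold ratio (log2 fold change -1.72, SE 0.40, adjusted p = 0.0244), and kept its call only without WT_12h replicate 3. Zm00001d022081.RefGen_V4 lost its call without WT_12h replicate 1 or 2, and Zm00001d044156.RefGen_V4 kept it only without A_12h replicate 1 or 2. Both also lost it by limma-voom (adjusted p = 0.188 and 0.661, the latter with a log2 fold change of 6.25), and Zm00001d044156.RefGen_V4 with only the groups compared in the fit (adjusted p = 0.0771). Their log2 fold changes were 14.36 without WT_12h replicate 3 and 10.49 without WT_12h replicate 2, respectively. A total of 1356 genes passed the threshold, 813 higher and 543 lower in line A. Of these, 436 were higher and 40 lower by at least 2-fold. With only the groups compared in the fit the count was 1034, 729 higher and 305 lower, and DESeq2 called 3114. Between the groups, 36.7% of genes did not overlap, where chance gives 10%. The count was 113, 86 and 1706 without WT_12h replicate 1, 2 or 3, 471, 456 and 847 without A_12h replicate 1, 2 or 3, and 9884 without the 6 libraries nearest to another group, which included 1354 of the 1356 genes with the same direction. In that last fit the log2 fold changes were 14.78 for Zm00001d022081.RefGen_V4, 4.25 for Zm00001d044156.RefGen_V4, -2.79 for Zm00001d050214.RefGen_V4 and -1.77 for Zm00001d022085.RefGen_V4.

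**Figure D2:**
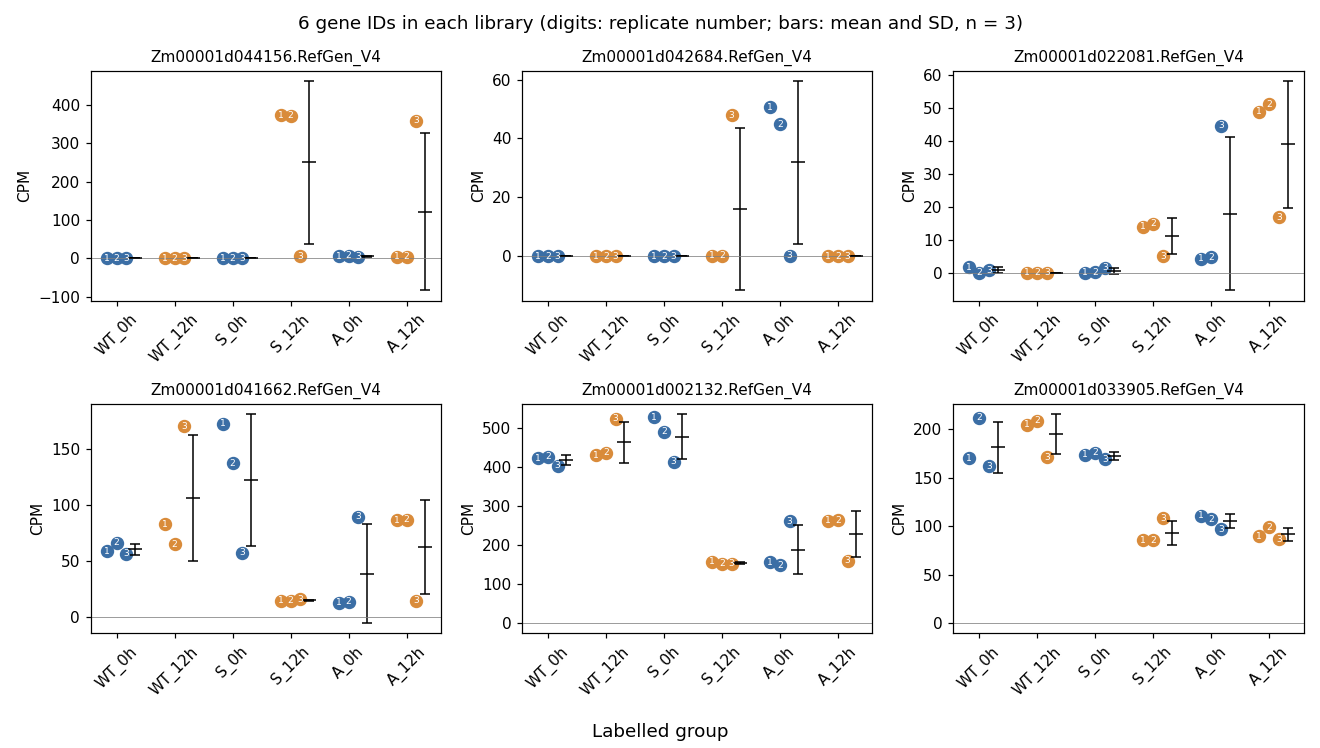
CPM of 6 gene IDs in every library by labelled group (blue, 0 h; orange, 12 h; the digit is the replicate number), with the mean and SD of the 3 libraries as a black bar. For Zm00001d044156.RefGen_V4, S_12h replicates 1 and 2 and A_12h replicate 3 lie between 359 and 374 CPM and every other library at 6.51 CPM or below.

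The difference between line S and WT in the response to hypoxia passed the threshold for 22 of 20945 genes, 18 with a larger and 4 with a smaller log2 change in line S. Zm00001d036761.RefGen_V4 went from 0.193 ± 0.0947 to 11.7 ± 11 CPM in line S and from 0.291 ± 0.116 to 0.147 ± 0.0708 CPM in WT (SD, n = 3; difference of log2 changes 6.88, SE 1.13, adjusted p = 0.0302). Zm00001d030998.RefGen_V4 went from 3.0 ± 0.614 to 19.0 ± 4.36 CPM in line S and from 2.63 ± 0.159 to 2.46 ± 0.856 CPM in WT (difference 2.75, SE 0.39, adjusted p = 0.0221). Zm00001d002132.RefGen_V4 went from 476.9 ± 58 to 152.9 ± 2.94 CPM in line S and from 416.1 ± 12.9 to 462.8 ± 52.6 CPM in WT (difference -1.79, SE 0.29, adjusted p = 0.0302). Zm00001d033905.RefGen_V4 went from 172.7 ± 3.78 to 92.9 ± 12.8 CPM in line S and from 181.5 ± 26.7 to 195.2 ± 20.8 CPM in WT (difference -1.0, SE 0.16, adjusted p = 0.0302). The count of 22 was 2, 43 and 4 without WT_0h replicate 1, 2 or 3, 3, 3 and 12 without WT_12h replicate 1, 2 or 3, 2, 4 and 55 without S_0h replicate 1, 2 or 3, and 2, 2 and 1211 without S_12h replicate 1, 2 or 3. Of these 12 omissions, the calls of the 4 IDs were kept in 2, 5, 3 and 4 respectively, always including those of S_0h replicate 3 and S_12h replicate 3. The difference for Zm00001d036761.RefGen_V4 was 5.75 without S_12h replicate 3. Its call and that of Zm00001d030998.RefGen_V4 were lost by limma-voom (adjusted p = 0.412 and 0.0622). With the replicate number as a block in the edgeR fit, all 4 IDs lost their call (adjusted p = 0.0759 to 0.108). The count was 41 with RLE factors, 49 with the stricter filter and 149 with only the groups compared in the fit, where 73 had the larger and 76 the smaller change in line S. DESeq2 called 807 genes, 60.5% of them with the larger change in line S against 81.8% by edgeR. Without the 6 libraries nearest to another group edgeR called 9193, 4727 with the larger and 4466 with the smaller change (51.4% larger), including all 22 with the same direction and with differences of 4.90, 3.17, -1.80 and -1.34 for the 4 IDs.

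Between line A and WT, no gene passed the threshold for a difference in the response to hypoxia by edgeR (0 of 20945, lowest adjusted p = 0.689, with 1089 genes at an unadjusted p under 0.05), limma-voom called 0 and DESeq2 called 14. The count stayed at 0 without any 1 of the 12 libraries and was 10055 without the 6 libraries nearest to another group.

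Between lines A and S, the difference in the response passed the threshold for 257 genes, 106 with a higher and 151 with a lower log2 change in line A. Zm00001d018340.RefGen_V4 went from 4.45 ± 2.86 to 7.02 ± 2.41 CPM in line A and from 13.7 ± 3.83 to 3.99 ± 1.33 CPM in line S (SD, n = 3; difference of log2 changes 2.43, SE 0.55, adjusted p = 0.0495). Zm00001d015008.RefGen_V4 went from 23.6 ± 10.4 to 30.1 ± 12.1 CPM in line A and from 48.7 ± 6.95 to 15.96 ± 0.936 CPM in line S (difference 1.96, SE 0.45, adjusted p = 0.0495). Zm00001d036609.RefGen_V4 went from 49.4 ± 42.8 to 0.0184 ± 0.016 CPM in line A and from 0.0493 ± 0.0392 to 24.6 ± 42.6 CPM in line S (difference -20.33, SE 4.19, adjusted p = 0.0468). Its level was 74.7, 73.5 and 73.8 CPM in A_0h replicates 1 and 2 and S_12h replicate 3 and at most 0.135 CPM in the other 15 libraries, so its fitted difference depends on the prior count and on S_12h replicate 3, without which it was -11.17 (adjusted p = 0.266). Zm00001d042684.RefGen_V4 was detected above 0.218 CPM in the same 3 libraries alone (difference -19.31, SE 3.69, adjusted p = 0.0426), and its difference was -12.6 (adjusted p = 0.0638) without S_12h replicate 3. The count was 17, 1 and 13 without S_0h replicate 1, 2 or 3, 399, 350 and 89 without S_12h replicate 1, 2 or 3, 4, 4 and 3837 without A_0h replicate 1, 2 or 3, and 1, 1 and 1253 without A_12h replicate 1, 2 or 3. Of the 12 omissions, the calls of the 4 IDs were kept in 3, 2, 4 and 4, always including those of A_0h replicate 3 and A_12h replicate 3. The difference for Zm00001d018340.RefGen_V4 was 3.10 without A_0h replicate 3. The count was 28 with no low-count filter, 71 with the stricter filter, 13 with only the groups compared in the fit, 132 by limma-voom and 1840 by DESeq2. The balance of directions was not stable: 1970 were higher and 1867 lower in line A without A_0h replicate 3, and 45 and 44 without S_12h replicate 3. In contrast, 91 were higher and 308 lower without S_12h replicate 1, and 2 and 11 with only the groups compared in the fit. Both higher IDs had an adjusted p of 0.0504 with RLE factors and 0.0526 with the stricter filter. All 4 IDs lost their call with no low-count filter (adjusted p = 0.0535 to 0.0611) and with only the groups compared in the fit (0.133 to 0.148). By limma-voom Zm00001d015008.RefGen_V4 (0.0588), Zm00001d036609.RefGen_V4 (difference -10.04, adjusted p = 0.687) and Zm00001d042684.RefGen_V4 (difference -12.55, adjusted p = 0.556) lost theirs. For the higher IDs with 1 library left out, adjusted p ran from 0.00242 to 0.16 for Zm00001d018340.RefGen_V4 and from 0.00363 to 0.16 for Zm00001d015008.RefGen_V4. The count was 10520 (5594 higher, 4926 lower) without the 6 libraries nearest to another group, including all 257 genes with the same direction. The differences of the 4 IDs were then 2.91, 2.84, -12.92 and -12.24.

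**Figure D3:**
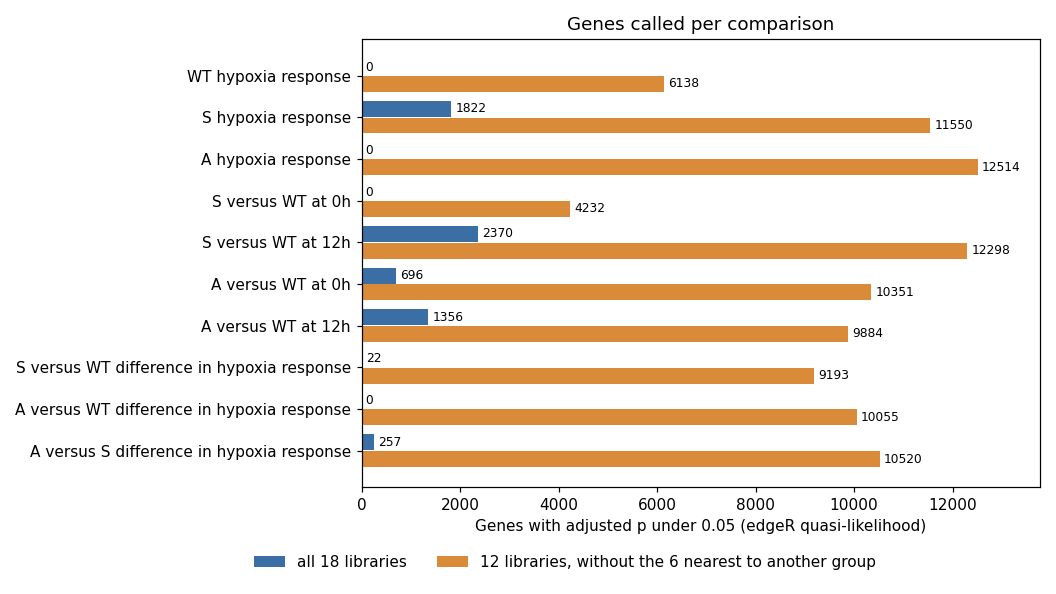
Genes with an adjusted p under 0.05 by edgeR in each of the 10 comparisons, with all 18 libraries (blue) and with the 12 libraries left after removing the 6 that were nearest to another labelled group (orange). Counts run from 0 to 2370 with all libraries and from 4232 to 12514 with 12.

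The 3 hypoxia comparisons share no library. Across the 20945 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.04 between WT and line S, 0.05 between WT and line A and -0.52 between lines S and A. By rank, Spearman's rho over the same genes was 0.13, 0.15 and 0.04, so the negative value for lines S and A was not seen in the ranks. S_12h replicate 3 and A_0h replicates 1 and 2, which resemble each other, enter the last pair on opposite sides, and without the 6 libraries nearest to another group its r was 0.08, with 0.13 for WT and line S and 0.00 for WT and line A (rho 0.17, 0.13 and 0.02). In that fit 7592 genes were called in both lines S and A, 69.6% of them in the same direction. In both lines 2815 were higher and 2470 lower, where lists drawn independently would share 1795 and 1642. For WT and line S it was 4273 genes and 67.3%, with 1450 higher and 1426 lower in both against 789 and 896 for independent lists. For WT and line A it was 4249 genes and 56.7%, with 1298 higher and 1112 lower against 884 and 937. The values for independent lists, here and below, take every gene as equally likely to be called. Part of the excess may therefore come from genes that are easier to call in any comparison, which was not tested. With all libraries, no overlap of calls could be counted, since WT and line A had none.

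At 12 h, 512 genes were higher and 408 lower in both line S and line A than in WT, where lists drawn independently would share 50.5 and 27.7, and no gene was called in opposite directions. Both comparisons use the same WT libraries, and 3 of them do not give separate sets of at least 2 for each line, so part of this excess may come from the shared controls. A_12h replicate 3, whose nearest libraries are S_12h replicates 1 and 2 (rho 0.9974 and 0.9973), also enters the overlap on the side of line A. Across genes, the log2 fold changes of the 2 lines correlated at r = 0.52 (rho 0.67). For simulated unchanged groups with shared controls r was 0.49. The covariance of the 2 lines was 0.713 against 0.237 simulated, a difference of 0.476. All simulated libraries, WT included, had 1 mean per gene and a dispersion estimated over all 6 groups. Their scatter is not that of the real WT libraries, so the simulated values may be too high or too low for the shared part. Without the 6 libraries nearest to another group, 3715 genes were higher and 3225 lower in both lines, where independent lists would share 1634 and 1265. The r was then 0.69 (rho 0.63), with no simulation of that fit. At 0 h, r was 0.17 (rho 0.24) against 0.50 simulated and the covariance 0.154 against 0.237, a difference of -0.083. Because of that scatter, neither this difference nor the one at 12 h decides whether the 2 lines changed alike beyond the shared controls. With the 6 libraries left out, 696 genes were higher and 850 lower in both lines at 0 h against 512 and 529 for independent lists, and r was 0.18 (rho 0.14).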

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

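The tests on other splits of the libraries were chosen after the number of genes called was known. The difference between line S and WT in the response to hypoxia was past the threshold for 22 genes, and that between lines A and S for 257. The IDs named for them differed in log2 change by 6.88 for Zm00001d036761.RefGen_V4, 2.75 for Zm00001d030998.RefGen_V4, -1.79 for Zm00001d002132.RefGen_V4 and -1.0 for Zm00001d033905.RefGen_V4 (line S minus WT). For line A minus line S they differed by 2.43 for Zm00001d018340.RefGen_V4, 1.96 for Zm00001d015008.RefGen_V4, -20.33 for Zm00001d036609.RefGen_V4 and -19.31 for Zm00001d042684.RefGen_V4. The last 2 values rest on S_12h replicate 3, without which they were -11.17 (adjusted p = 0.266) and -12.6 (adjusted p = 0.0638). All are interaction terms of the model and were noted because they compare the responses of 2 lines to the same treatment.

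Other splits of the same libraries were refitted to see whether chance can be excluded. For the differences between responses, 30 splits each were drawn by shuffling the line labels within each time, the real one included. For line S against WT, 2 of 30 gave at least the real 22 genes, with 42 in the highest other split. That split kept both 12 h groups whole and shuffled only the 0 h libraries, so it kept the difference between the lines at 12 h. Splits shuffled at each time separately can hold a line effect. Their shares therefore neither exclude chance nor show that it gives 22 genes. For line A against WT, 30 of 30 gave at least the real count of 0, below which no count can fall, so this tests nothing. The highest other split also gave 0. For line A against S, 3 of 30 gave at least 257, and the highest gave 5805, a share that again does not decide about chance. That split exchanged all S_0h with all A_0h libraries. At 12 h it placed S_12h replicate 3 with A_12h replicates 1 and 2, and A_12h replicate 3 with S_12h replicates 1 and 2. With the lines exchanged at 0 h, its contrast adds the line differences at 0 h and 12 h, where the real one subtracts them. The count of 5805 is therefore no value for chance, and it does not show what the regrouping at 12 h did. The set of A_12h replicate 3 with S_12h replicates 1 and 2 was already seen in the nearest libraries, from the same counts, and adds no separate support for a structure of the samples. The other set was not: S_12h replicate 3 is nearest to A_0h replicates 1 and 2 (rho 0.9972 and 0.9971), and its rho with A_12h replicates 1 and 2 was 0.9495 and 0.9494.

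For the 7 comparisons of 2 groups, the 10 possible splits are too few for a share under 0.05. The response in line S had 1822 calls and the highest other split 0, reached by 1 of 10 splits. For S against WT at 12 h these values were 2370, 0 and 1 of 10, for A against WT at 0 h 696, 0 and 1 of 10, and for A against WT at 12 h 1356, 0 and 1 of 10. Where the labels gave 0 calls, all 10 of 10 splits gave as many, which was fixed in advance since no count can fall below 0. The highest other split gave 982 for the response in WT, 2153 for that in line A and 26 for S against WT at 0 h. The split with 982 joined WT_0h replicate 2 with WT_12h replicates 1 and 2, the one with 2153 joined A_0h replicate 3 with A_12h replicates 1 and 2, and the one with 26 joined S_0h replicate 3 with WT_0h replicates 1 and 3. Each of these joins libraries already found nearest to each other, so these counts restate that structure of the samples and do not test it.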

How the results depend on the processing

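One alternative, leaving out the 6 libraries nearest to another group, was chosen after seeing the data, and the others were planned. None of the 24 calls of IDs named by the fixed rule changed direction where an alternative gave them a value (DESeq2 and the stricter filter did so for 19 each, the fit of only the groups compared for 22), and the 12 IDs chosen from the fit without the 6 libraries were not run under the alternatives. No gene called with all libraries was called in the opposite direction. Counts are given in the order response in WT, S and A, S against WT at 0 h and 12 h, A against WT at 0 h and 12 h, and difference of responses S against WT, A against WT and A against S. With all libraries they were 0, 1822, 0, 0, 2370, 696, 1356, 22, 0 and 257. Without the 6 libraries they were 6138, 11550, 12514, 4232, 12298, 10351, 9884, 9193, 10055 and 10520. The selection lowers the spread in that fit, to an extent that was not measured. DESeq2 gave 7, 3769, 171, 13, 4058, 2305, 3114, 807, 14 and 1840, for which the cause was not tested. Leaving out 1 library at a time gave 0, 228 to 6074, 0 to 5112, 0, 353 to 5990, 159 to 3083, 86 to 1706, 2 to 1211, 0 and 1 to 3837. The highest values came without S_12h replicate 3 (6074, 5990 and 1211), A_0h replicate 3 (5112, 3083 and 3837) and WT_12h replicate 3 (1706), 3 of the 6 libraries. With only the groups compared in the fit, and so fewer libraries to estimate the spread, counts above 0 became 166 for the response in S, 85 for S against WT at 12 h, 33 for A against WT at 0 h, 149 for the difference S against WT and 13 for A against S. For the difference S against WT, RLE factors gave 41 and the stricter filter 49. For A against S, no filter gave 28, the stricter filter 71 and limma-voom 132, and the cause was not tested. The other counts moved by less than 1.5 times under these settings.

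With the replicate number as a block, calls were 790 for the response in S, 1284 and 577 for S and A against WT at 12 h, 285 for A against WT at 0 h, 2 for the difference S against WT, 1 for A against S and 0 elsewhere. Of the 45 same-numbered pairs 4 had deviations from their group means that correlated above 0.1 (range -0.77 to 0.54), and 4 of the 18 libraries correlated best with one of their own number. These values cannot show whether the numbers pair the samples. The group means include the 6 libraries nearest to another group, replicate 3 in every group but WT_0h, and those libraries shape the deviations. Of the 24 calls of IDs named by the fixed rule, 22 stayed past the threshold with RLE factors, 16 with no filter, 8 with the block, 8 with limma-voom and 24 without the 6 libraries, and 10 of 22 tested with only the groups compared, 17 of 19 with the stricter filter and 19 of 19 with an adjusted p in DESeq2. DESeq2 gave no adjusted p for Zm00001d044156.RefGen_V4 in any comparison that names it. It also gave none for Zm00001d011394.RefGen_V4 in A against WT at 0 h and Zm00001d036609.RefGen_V4 in A against S. These calls are thus neither kept nor lost in DESeq2. A call kept says nothing of its size: without the 6 libraries the log2 fold change went from 9.73 to 2.41 for Zm00001d042684.RefGen_V4 in the response of S and from 9.55 to 4.25 for Zm00001d044156.RefGen_V4 in A against WT at 12 h. Depth limits the low end: genes under 0.0334 to 0.0846 CPM, by library, rest on 3 counts or fewer.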

Other observations

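All tests in this part were chosen after the result was seen, except the thinning of every library to the same depth. The test of depth for the 26 genes below was also chosen afterwards. A set of 26 genes was on (at least 10 CPM) in A_0h replicates 1 and 2 and off (at most 3 counts) in A_12h replicates 1 and 2, at a mean of 10.9 to 73.9 CPM with a median of 19.2 CPM, while 1 gene ran the other way. Zm00001d011601.RefGen_V4, at 73.3 CPM, and Zm00001d032472.RefGen_V4, at 61.9 CPM, are 2 of them. The other library that held these genes was S_12h replicate 3, and the median over the 26 genes was 0% of the A_0h level in each of the other 15 libraries. Among the 12 libraries that were not nearest to another group, 28 genes were on in A_0h and off in WT_0h and 29 were on in A_0h and off in S_0h, against 0 between WT_0h and S_0h in either direction and 11 on in WT_0h and off in WT_12h.

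The first pattern is that libraries group in 6 sets of 3 that cross the labels. Unequal depth is argued against: with every library thinned to 35441975 counts, 18 of 18 libraries kept the same 2 nearest libraries. Partial mixing of samples is also argued against, since over the genes that differ at least 4-fold between a library's labelled partners and the libraries it resembles, the 6 libraries lay at a median of at most 0.64% of the way to their partners. Exchanged labels of samples or columns may explain it: 6 of 6 libraries had both nearest libraries in 1 other group and each group had lost 1 library and received 1, which an exchange needs, though these neighbours were seen before the explanation was put. Which library belongs where, at which step an exchange would have happened, and a grouping by plants, dissection or sequencing day that the labels do not record all stay open, and no biological explanation was tested.

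The second pattern is the 26 genes that are on in A_0h replicates 1 and 2 and off in A_12h replicates 1 and 2. Low depth of the libraries without them is argued against: of the libraries not used to choose the genes, 11 had higher totals than A_0h replicates 1 and 2, and 11 of 11 were at a median of 0% of their level. Switching off by 12 h of hypoxia in line A stays open: in S_12h replicate 3, labelled hypoxic, the genes were at a median of 99.8% of the A_0h level, and in A_0h replicate 3, labelled normoxic, at 0%, but these are 2 of the 6 libraries whose labels are in doubt. Plant material of another genetic background in the 3 libraries, which may carry genes that the others lack, was not tested and stays open too.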
